A study of Mus musculus with 140 samples.

How the data were processed

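The study screened mouse silencers, DNA elements that lower transcription, with Ss-STARR-seq. In this assay sheared genomic fragments are cloned into a reporter plasmid, the plasmid library is transfected into cells, and reporter RNA is sequenced beside the plasmid library itself. The labels describe 140 sequencing libraries. Of these, 20 came from the input plasmid library, 64 from reporter RNA of mouse embryonic fibroblasts (MEFs) and 56 from reporter RNA of mouse embryonic stem cells (mESCs). The MEF libraries carried 4 output set numbers with 16 libraries each. The mESC libraries carried 3 output set numbers (2, 4 and 5) with 20, 20 and 16 libraries. The labels name 1 interval list for each cell type, and the input libraries are named with both lists. The MEF list and the mESC list were the 2 tables analysed. Values per library, the CRISPR knockout experiments and the other omics data that the design text mentions were not analysed here.

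Each list gives a chromosome, a start, an end and a fold per interval. The fold is a linear ratio that the authors deposited with each interval, per the file headers. Which libraries were divided by which, any scaling for depth, the caller and the treatment of replicates are not given in the sources used here. Reads were aligned with Bowtie2 and handled with SAMtools, per the submitters' processing notes, which give no versions. Those notes name the build hg38, while the series design text names mm10. No interval of either list ended beyond an mm10 chromosome (0 in each list), all chromosome names were mouse names, and mm10 was used throughout. Coordinates are printed as the lists give them. About 40.7% of the starts in the MEF list lay 1 base past a multiple of 50 bp, so the starts may count from 1, which leaves an uncertainty of 1 bp. The authors' fold was used only to describe, rank and halve intervals within a list. The lists hold no counts, so the depth behind an interval is unknown and no interval could be given an error of its own.

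Sequence and soft-masked repeats came from GRCm38.p6, the assembly that mm10 displays, and gene models came from the GENCODE M21 basic annotation. An interval was called shared where it overlapped the other list by at least 1 bp and list-only otherwise. Overlap, clustering and annotation were compared with 100 random placements of the intervals on their own chromosomes, keeping lengths and avoiding assembly gaps. The permutation p was two-sided and not adjusted for the number of tests, and 0.0198 was the smallest value these placements could give. Clustering was the share of intervals with a neighbour of the same list within 5 kb. Annotation was assigned at the interval midpoint in the order promoter (1 kb either side of a transcription start site, TSS), 5 prime UTR, coding exon, 3 prime UTR, other exon, intron and intergenic. Composition was compared with 1 placement set, with 95% bootstrap intervals from 1000 draws, or 500 draws for CpG. Fold medians of shared and list-only intervals were compared with a two-sided permutation test of 100000 resamples, as was the correlation of both lists across 1 Mb autosomal bins, permuted within chromosomes.

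A gene's territory was its body plus 10 kb on each side, and an interval in overlapping territories counted for each gene, in list totals too. For each of 3544 protein-coding genes with at least 10 intervals, the mESC share was tested against the genome-wide share with a two-sided exact binomial test and Benjamini-Hochberg adjustment at 0.05. The same test was run on 1 Mb bins. Gene lists were fixed before the data were examined. The 14 lists were compared with 10000 random lists of the same size matched on territory length, with two-sided permutation p-values adjusted over 42 tests. The smallest unadjusted p these lists could give was 0.0002. A set of 26 consensus motifs was searched on both strands in 300 bp windows centred on MEF-only, mESC-only and shared intervals and in random windows matched on GC. Most intervals were no longer than the window, so a match can lie in the sequence beside the listed interval, and whole intervals were an alternative. Two-sided Fisher exact tests were adjusted over 104 tests.

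The named genes followed a rule set before the data were examined. It took up to 10 genes in each direction past 0.05 in the per-gene test, the 3 genes with the most MEF and the 3 with the most mESC intervals per Mb, the 3 members of each list with the most intervals, and a fixed set of genes for pluripotency, reprogramming and fibroblast identity. The 3 intervals with the highest fold in each list were named by position.

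The tests were tried on simulated data. The per-gene test used the real interval totals of the 3544 genes with mESC counts drawn independently. Of 200 genes given an odds ratio of 4, 17% were recovered, and of 200 given an odds ratio of 8, 43.5%. There was 1 false call each, and 0 genes were called with no change. Of 200 random lists of 35 genes, 4% passed an unadjusted 0.05 with no change and 97.5% with a doubled density. All of 250 AP-1 sites planted in 5000 windows were found. A planted overlap of 1000 among 4000 intervals was found in full, beside 74 overlaps that were not planted. Full recovery was certain from the planting, so these cases checked the motif search and the overlap count, not the tests. With none planted, 104 of 4000 intervals overlapped (permutation p = 0.772).

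Alternatives covered the overlap that counts as shared, circular shifts and GC-matched placement, the intervals at or above the median fold, neighbour distances of 1 and 20 kb, other promoter windows and gene territories, other minimum counts, merged neighbours, other bin sizes, other motif windows and backgrounds. Error bars of motif ratios are 95% intervals on the log scale from the match counts. Alternatives added after the data were seen used list-only intervals, gene lists shifted along the gene order, and placement matched on GC and soft-masked share. The shifted lists keep neighbouring genes together but were not matched on territory length. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and numba 0.67.0.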

Results

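The data comprised 2 lists of silencer intervals, 1 for MEFs, the differentiated cells from which induced pluripotent stem cells are commonly made, and 1 for mESCs, which are pluripotent. The series asked where silencers lie in each cell type and whether the cell types share them. The MEF list held 89596 intervals covering 19.6 Mb, or 0.742% of the ungapped mm10 genome. The mESC list held 115165 intervals covering 26.0 Mb, or 0.981%. The median interval length was 200 bp in both lists, with a longest interval of 1800 bp in MEFs and 1850 bp in mESCs. Every listed fold lay above 2. The median authors' fold was 2.36 in MEFs and 2.42 in mESCs, and 5.92% of MEF and 7.99% of mESC intervals had a fold above 4. There was 1 list per cell type, so no difference between cell types had a replicate check. The p-values below describe these lists, since intervals, genes and bins are not replicates.

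The 3 MEF intervals with the highest fold were intergenic and all overlapped an mESC interval. Which libraries were divided by which is not given, so a high fold is not read here as strong silencing. The first, chromosome 5 from 8372301 to 8372551, had a fold of 84.4 in MEFs and 14.5 in mESCs and lay 4.14 kb from Adam22, a gene for a neuronal membrane protein. The second, chromosome 3 from 54929901 to 54930151, had folds of 76.2 and 25.3 and lay 14.0 kb from Sertm1. The third, chromosome 1 from 64368675 to 64368825, had nearly equal folds of 59.9 in MEFs and 59.6 in mESCs, 164 kb from Creb1. In mESCs the interval with the highest fold was at chromosome 1 from 136702251 to 136702551, in an intron of the lincRNA gene Platr22 and 72.2 kb from Zfp281. Its fold was 116.5 in mESCs and 5.99 in MEFs. The next were chromosome 11 from 34787280 to 34787517, 3.39 kb from Dock2, with a fold of 92.1 in mESCs and 5.22 in MEFs, and chromosome 2 from 176818054 to 176818304, 6.83 kb from Gm14295, with 81.3 and 11.3. Soft-masked repeat made up 100%, 16.4% and 30.7% of the 3 MEF intervals and 100%, 83.5% and 100% of the 3 mESC intervals, in this order. Folds of the 2 lists were scaled in ways not given in the sources used here, so these pairs of values are not a measured change.

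Many silencers were listed in both cell types. Of the MEF intervals, 42378 (47.3%, 95% exact binomial interval 47.0 to 47.6) overlapped an mESC interval, and 42186 mESC intervals (36.6%, 36.4 to 36.9) overlapped a MEF interval. Random placement gave 2.03% and 1.58%, so the observed overlap was 23.3 and 23.1 times the random value (p = 0.0198 for each, the smallest that 100 placements can give). The ratio was larger for overlap of at least 50% of both intervals (76.5 and 77.1 times) and smaller for midpoints within 1 kb (6.20 and 6.24 times). With both lists cut to intervals at or above their median fold, the overlapping shares were 40.1% and 31.1%. The cut removed possible partners from the other list, so these shares do not show less sharing at high fold. The ratio was 41.6 and 41.4 times because the shorter lists lowered the random shares (0.965% in MEFs). The remaining 47218 MEF-only and 72979 mESC-only intervals had no counterpart in the other list. Since the lists hold only folds above 2, this does not show that the other cell type lacked the activity. The Jaccard index of covered bases was 0.247 against 0.00455 at random, and 3730 intervals had the same start and end in both lists. Shared intervals had a higher authors' fold than list-only intervals, with medians of 2.46 against 2.29 in MEFs and 2.53 against 2.36 in mESCs (permutation test, p = 1e-05 for each, the smallest that 100000 resamples can give). The overlapping share was 32.2% among the weakest 10% of MEF folds and 56.5% among the strongest 10%, and 23.8% and 42.4% in mESCs. Over 42911 overlapping pairs the MEF and mESC folds rose together (Spearman rho = 0.498, Pearson r of log2 folds = 0.605; permutation p = 1e-05 for rho, the smallest possible). The input libraries are named with both lists. If both lists were made against the same input, chance in it can place the same interval in both. The lists hold no counts, so this part could not be simulated or removed by splitting the input.

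**Figure D1:**
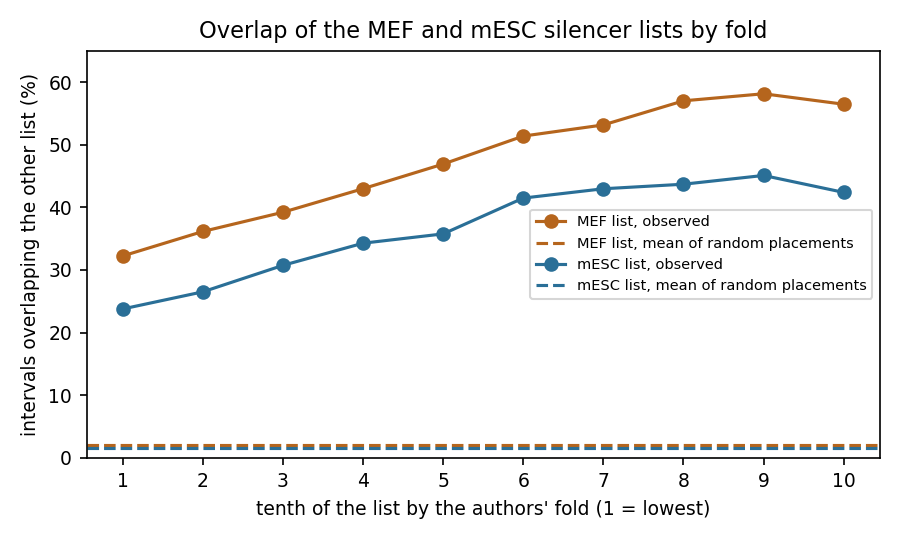
Percent of intervals that overlap the other list (vertical axis) by 10% steps of each list ranked on the authors' fold (horizontal axis), for the MEF list and the mESC list. Points are observed shares and dashed lines the means of 100 random placements, at 2.03% for MEFs and 1.58% for mESCs; the observed shares lie far above them in every step.

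Along the genome the lists had the same layout. Autosomes held 36.6 MEF and 47.1 mESC intervals per Mb, with the fewest on chromosome 7 (32.0 and 42.0) and the most on chromosome 10 (40.1 and 51.5). The X chromosome held 10.8 MEF and 13.8 mESC intervals per Mb, 3.40 and 3.42 times fewer than the autosomes. The Y chromosome, 96.3% of which is soft-masked, held 30 MEF and 38 mESC intervals. Among intervals at or above the median fold the X deficit was smaller, at 2.56 and 2.49 times. The mESC share of intervals ranged from 55.6% to 56.8% over chromosomes, and no chromosome differed from the others (chi-square test over chromosomes, p = 0.965; 0 of 21 chromosomes past an adjusted Fisher exact p of 0.05). With list-only intervals the chi-square p was 0.617, again with 0 chromosomes past 0.05.

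**Figure D2:**
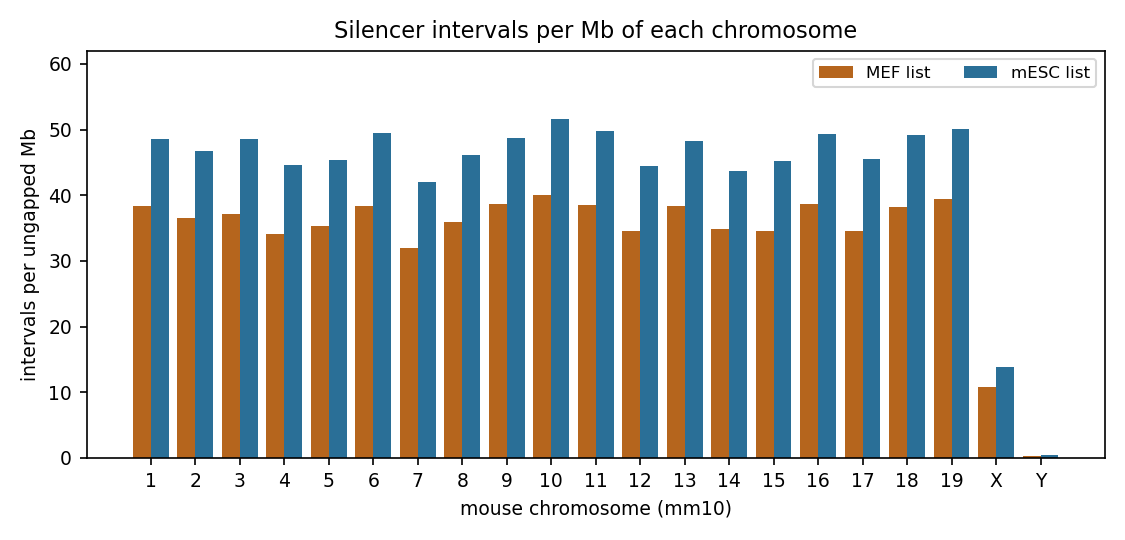
Silencer intervals per ungapped Mb (vertical axis) for each mouse chromosome of build mm10 (horizontal axis), with paired bars for the MEF and mESC lists. The X bars stand at 10.8 and 13.8 per Mb, against 36.6 and 47.1 over the autosomes.

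Within chromosomes the intervals gathered moderately. A neighbour of the same list lay within 5 kb of 39.3% of MEF and 45.8% of mESC intervals, 1.25 and 1.19 times the random share (p = 0.0198 for each). Within 1 kb the excess was 1.95 and 1.74 times. The placements did not follow the coverage of the plasmid library, so uneven coverage was not separated from clustering of silencers. Nor were single regions that may be listed as several adjacent intervals. Across 2454 autosomal bins of 1 Mb, the MEF and mESC counts followed each other (Spearman rho = 0.797, Pearson r = 0.855; permutation p = 1e-05 for each; 2 correlations, so the adjusted values are the same). The correlation is across bins of 2 lists that share many intervals, and uneven coverage of the plasmid library was not separated from it. No bin had an excess of either cell type (0 toward MEFs and 0 toward mESCs of 2537 tested with the exact binomial test, 43 at an unadjusted p under 0.05). Shared intervals count in both lists and pull every share toward the middle, with a variance between bins of 0.66 times that of independent counts. With list-only intervals the variance was 1.13 times, and still 0 of 2493 bins passed in either direction, with 131 at an unadjusted p under 0.05.

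Listed intervals lay less often in coding sequence and promoters, and slightly more often in introns, than random placements. The placements were drawn from the ungapped genome, not from the sequence that the plasmid library covered. Uneven library coverage was therefore not separated from silencer activity. Coding exons held 479 MEF intervals (0.535%) and 610 mESC intervals (0.530%), 0.455 and 0.451 times the random share. Promoters held 3.40% and 3.51%, or 0.768 and 0.792 times random, and promoters of protein-coding genes 0.625 and 0.650 times. Introns held 43.7% and 44.0% (1.07 and 1.08 times) and intergenic sequence 50.6% and 50.3% (0.975 and 0.969 times), with p = 0.0198 for all of these. The 3 prime UTRs held 1.24% and 1.19%, which did not differ from random (p = 0.515 and 0.455). Against GC-matched placement the MEF share was 1.12 times random (unadjusted p = 0.0198). The promoter deficit ended with promoters of 5 kb either side (0.990 and 0.997 times, p = 0.178 and 0.634), and the intergenic deficit ended among intervals at or above the median fold (0.998 and 0.995 times, p = 0.535 and 0.297). With GC-matched placement the promoter deficit shrank to 0.949 and 0.965 times (unadjusted p = 0.0198 and 0.0396). That of coding exons shrank to 0.699 and 0.671 times (unadjusted p = 0.0198 for each). MEF-only and mESC-only intervals did not differ in any category (smallest adjusted Fisher exact p = 0.232), with 3.55% and 3.67% in promoters and 43.6% and 44.2% in introns.

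**Figure D3:**
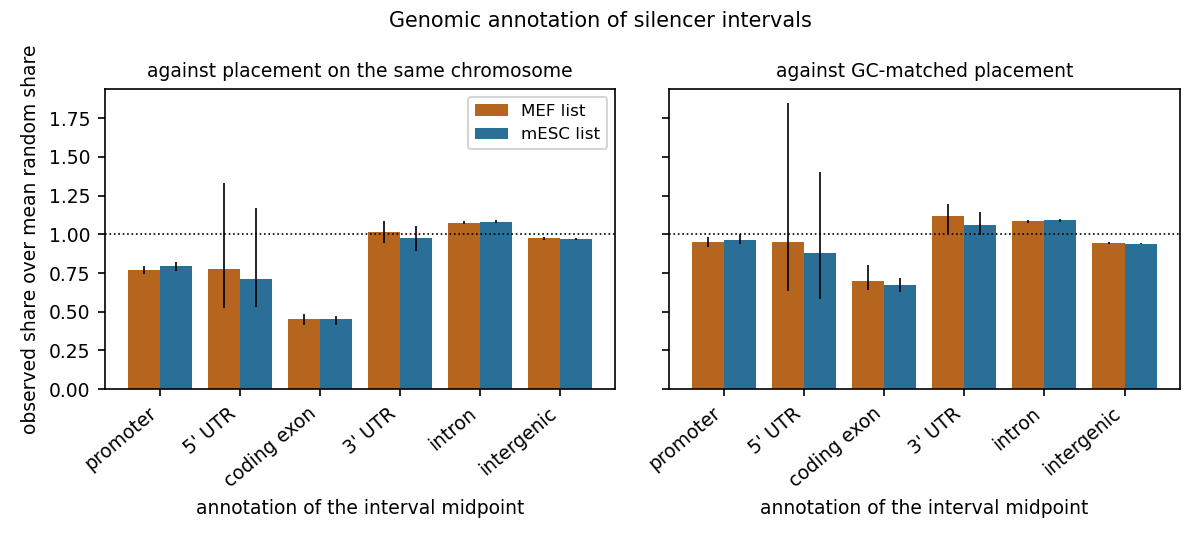
Observed share of interval midpoints in each annotation class over the mean share of 100 random placements (vertical axis, 1 means as at random), for placement on the same chromosome and for GC-matched placement. Bars are the MEF and mESC lists and error bars span the lowest to the highest placement; coding exons stand at 0.455 and 0.451 on the left and at 0.699 and 0.671 on the right.

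Listed intervals were poorer in GC and richer in repeats than random sequence. A reporter library and PCR depend on GC, and repeats depend on mapping. Coverage of the plasmid library was not available, so these effects were not separated from silencer activity. GC was 40.1% in MEF intervals against 41.9% at random, a difference of -1.76 percentage points (95% bootstrap interval -1.83 to -1.69), and 40.3% in mESC intervals, a difference of -1.58 (-1.65 to -1.52). Soft-masked repeats made up 38.5% of MEF and 40.9% of mESC sequence, 4.92 (4.63 to 5.23) and 7.12 (6.84 to 7.39) points above random. The excess of repeats was 1.55 points in MEF-only intervals and 6.20 points in mESC-only intervals, a difference of 4.65 points (95% interval 4.08 to 5.21). Shared MEF intervals stood 8.67 points above random. CpG observed over expected was 0.190 in both MEF-only and mESC-only intervals. It lay below random by a difference of -0.00356 in mESC-only intervals (-0.00592 to -0.00132), and the MEF-only interval of -0.00531 to 9.74e-05 reached 0.

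Motifs differed between windows centred on MEF-only and on mESC-only intervals. These classes rest on the listing alone, not on a measured absence of activity in the other cell type. The AP-1 site, bound by FOS and JUN factors that are active in fibroblasts, occurred in 5.67% of MEF-only windows and 4.46% of mESC-only windows, a ratio of 0.788 (Fisher exact test, adjusted p = 2.59e-19). The MYC-type E-box occurred in 3.06% and 2.48% (ratio 0.809, adjusted p = 1.37e-08), and the TEAD site in 5.19% and 4.71% (0.907, adjusted p = 0.00087). The NFI palindrome was rare, with 15 MEF-only and 5 mESC-only windows (0.216, adjusted p = 0.00721). The KLF/SP site went the other way, with 1.02% of MEF-only and 1.23% of mESC-only windows (1.21, adjusted p = 0.00364), as did the ZFP57 hexamer (1.35% and 1.58%, ratio 1.18, adjusted p = 0.00397). The BCL6/STAT site was more frequent in MEF-only windows (8.86% against 8.07%, ratio 0.911, adjusted p = 1.3e-05), as was a CpG (82.9% against 81.9%, ratio 0.988, adjusted p = 0.000107). The composite OCT4-SOX2 site of pluripotent cells occurred in 14 MEF-only, 18 mESC-only and 5 shared windows and did not differ between the list-only classes (adjusted p = 0.811). Neither did CTCF (70 and 104 windows, adjusted p = 0.953) or REST (1 and 6 windows, adjusted p = 0.496). With only windows under 50% soft-masked, the TEAD and ZFP57 differences did not pass (adjusted p = 0.0812 and 0.713). With whole intervals, those of BCL6/STAT, NFI and CpG did not (0.053, 0.0706 and 0.414). Whole intervals of the list-only classes were not matched on length, and a longer interval is likelier to hold a match.

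Against GC-matched random windows, the KLF/SP site was more frequent in MEF-only, mESC-only and shared intervals (1.45, 1.64 and 1.55 times, adjusted p = 1.6e-06, 2.59e-19 and 8.72e-08), though not in whole MEF-only intervals (1.11 times, adjusted p = 0.414). The SOX site was less frequent in mESC-only and shared intervals (0.909 and 0.834 times, adjusted p = 0.00426 and 2.14e-05), and the mESC-only deficit did not pass in whole intervals (0.943 times, adjusted p = 0.273) or in windows under 50% soft-masked (0.935 times, 0.120). The BCL6/STAT site was less frequent in all 3 classes (0.876, 0.800 and 0.781 times) and more frequent than in dinucleotide-shuffled sequence (1.16, 1.12 and 1.12 times). AP-1 stood at 1.23 times random in MEF-only windows (adjusted p = 5.57e-12), at 0.942 times in mESC-only windows (0.042) and at 1.03 times in shared windows (0.701). Against dinucleotide-shuffled sequence the AP-1 value of MEF-only windows was 0.983 times (adjusted p = 0.671), so its excess over background held for genomic windows and not for shuffled ones.

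**Figure D4:**
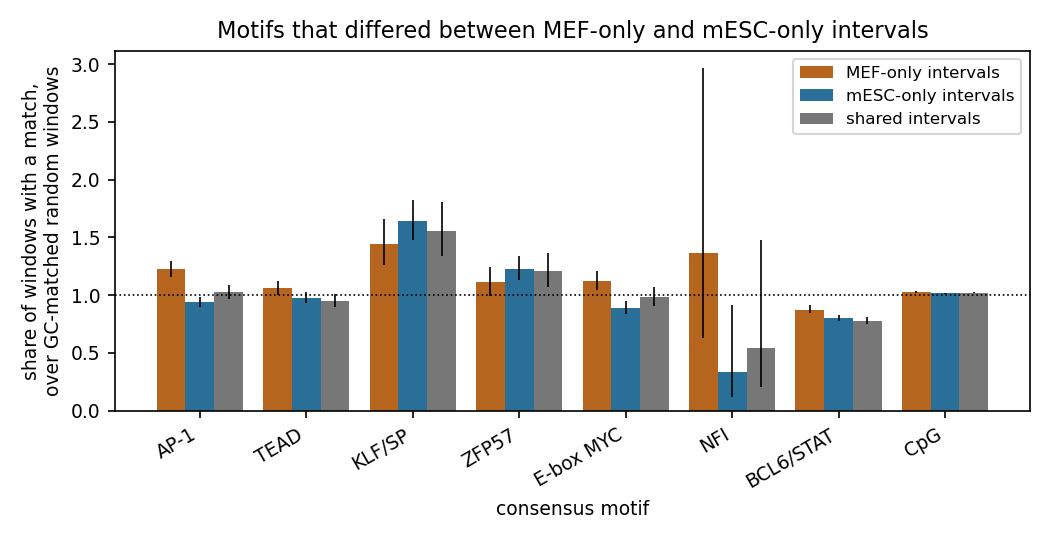
Share of 300 bp windows with at least 1 match over that of GC-matched random windows (vertical axis, 1 means as at random) for the 8 motifs that differed between MEF-only and mESC-only intervals (horizontal axis). Bars are MEF-only, mESC-only and shared intervals with 95% intervals of the ratio for counting error; AP-1 stands at 1.23, 0.942 and 1.03.

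No single gene had an excess of silencers of either cell type. Of 3544 protein-coding genes tested, 0 passed an adjusted exact binomial p of 0.05 toward MEFs and 0 toward mESCs, and 30 had an unadjusted p under 0.05, 13 of them toward mESCs. With list-only intervals 0 of 1662 genes passed, and 68 had an unadjusted p under 0.05. Adjusted over the list alone, 0 tested members of the fixed gene lists passed, but few members had enough intervals to be tested: 0 Hox and 0 lineage transcription factor genes, 1 of 1092 olfactory receptor genes, and at most 40 in any list (the Zfp genes). On simulated independent counts the test found 43.5% of genes with an odds ratio of 8. In the data, shared intervals count in both lists, and the variance between genes was 0.62 times that of independent counts. With list-only intervals it was 1.11 times. The simulated rates therefore do not give the power in the data, and differences by single genes may have gone undetected. The densest MEF territories were those of Actrt3 (7 MEF and 3 mESC intervals), Stx5a, a Golgi SNARE gene (10 and 5), and Pramel7, which is expressed in the inner cell mass (8 and 3). The densest mESC territories were those of Mrpl18, a mitochondrial ribosomal protein gene (3 MEF and 9 mESC intervals), Tatdn2 (7 and 12) and Tcp1, a subunit of the cytosolic chaperonin (5 and 10). Mrpl18 and Tcp1 overlap on chromosome 17, so part of their intervals are the same.

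Genes of fibroblast and mesenchymal identity lay by relatively more mESC silencers than random lists, a call that did not hold with list-only intervals or against lists shifted along the gene order. Their territories held 77 MEF and 138 mESC intervals, an mESC share of 64.2% against a median of 56.5% in matched random lists (ratio 1.14, permutation adjusted p = 0.0112). Of 35 members, 28 had more mESC than MEF intervals and 5 had fewer, where random lists had a median of 17 with more (12 to 23 in 95% of lists). This count restates the share and was chosen after the values were seen. The MEF density was 26.6 per Mb against 37.2 in random lists (0.716 times, adjusted p = 0.0908). The mESC density was 47.6 against 48.2 (0.989 times, adjusted p = 0.922). The MEF deficit passed within 25 kb of the TSS (0.569 times, adjusted p = 0.00735), but there the random lists were not matched on gene length. Runx2, a mesenchymal lineage factor, had 11 MEF and 15 mESC intervals, the extracellular matrix gene Fbn1 had 8 and 10, and Zeb1, a repressor of epithelial genes, had 11 and 9. Col1a1, the main collagen gene of fibroblasts, had 0 MEF and 3 mESC intervals, Twist1 had 1 and 2, Thy1 had 2 and 1, and Snai1 had none in either list (0 and 0). Leaving out any 1 member kept the share between 63.2% (without Cdh2) and 66.2% (without Zeb1). With list-only intervals the share was 71.0% against 61.1% in random lists (1.16 times, adjusted p = 0.0624), and against lists shifted along the gene order the ratio was 1.13 times (adjusted p = 0.105).

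Genes of chromatin repressors lay in silencer-dense territory in both cell types. The 35 members held 51.9 MEF intervals per Mb, 1.37 times random lists (adjusted p = 0.0437), and 73.7 mESC intervals per Mb, 1.49 times (adjusted p = 0.0028). Jarid2, a Polycomb cofactor, had 15 MEF and 20 mESC intervals, the nuclear receptor corepressor gene Ncor1 had 16 and 18, and Cbx5, which encodes heterochromatin protein HP1 alpha, had 11 and 13. Housekeeping genes were denser in mESC intervals (69.3 per Mb, 1.47 times, adjusted p = 0.0437), while their MEF density did not pass (50.7 per Mb, 1.44 times, adjusted p = 0.0792). Polr2a had 4 MEF and 8 mESC intervals, Tfrc 7 and 5, and Sdha 5 and 6. The mESC call of the chromatin repressors was lost among intervals at or above the median fold (1.42 times, adjusted p = 0.0588). Against lists shifted along the gene order it held (adjusted p = 0.0294). Their MEF call passed with GC matching (1.40 times, adjusted p = 0.0252) and under no other alternative, with ratios from 1.22 within 25 kb of the TSS to 1.48 among intervals at or above the median fold (adjusted p = 0.375 and 0.0551). The housekeeping mESC call passed under none of the alternatives, with ratios from 1.29 over gene bodies alone to 1.45 with list-only intervals (adjusted p = 0.518 and 0.122). The housekeeping MEF density passed within 25 kb of the TSS (1.42 times, adjusted p = 0.0378), against lists not matched on gene length.

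Hox genes had fewer mESC silencers than scattered random lists. This did not pass against lists that keep neighbouring genes together but are not matched on territory length. The 39 members held 24.1 mESC intervals per Mb against 44.8 in random lists (0.538 times, adjusted p = 0.0156) and 27.7 MEF intervals per Mb against 33.4 (0.828 times, adjusted p = 0.542). Hoxb2 had 4 MEF and 2 mESC intervals, Hoxb3 had 3 and 2, and Hoxc12 had 1 and 3. Within 25 kb of the TSS the MEF density was 0.635 times and the mESC density 0.556 times random (adjusted p = 0.0196 and 0.00168), also against scattered lists only. These lists were not matched on gene length. Hox genes lie in clusters whose territories overlap, so the same intervals count for several genes. The mESC deficit kept its size and did not pass against lists shifted along the gene order (0.500 times, adjusted p = 0.109), over gene bodies alone (0.536 times, 0.288) and with list-only intervals (0.502 times, 0.0605). It was smaller and did not pass with GC matching (0.665 times, 0.139) and among intervals at or above the median fold (0.671 times, 0.416).

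Against random lists, Zfp and olfactory receptor genes lay in denser and vomeronasal receptor genes in sparser silencer territory, and most of these calls depended on the setting. Zfp genes, a symbol family rich in KRAB zinc finger repressors, held 42.1 MEF and 58.2 mESC intervals per Mb, 1.14 and 1.19 times random lists (adjusted p = 0.0346 and 0.00336). Zfp407 had 27 MEF and 18 mESC intervals (unadjusted p = 0.0346, adjusted p = 1), Zfp521 had 16 and 19, and Zfp638 had 12 and 21. Olfactory receptor genes held 1.16 times the random MEF density (adjusted p = 0.0028) and 1.08 times the random mESC density (adjusted p = 0.0553); Olfr643 had 9 MEF and 12 mESC intervals, Olfr1076 had 5 and 4, and Olfr111 had 3 and 6. Vomeronasal receptor genes held 0.773 and 0.792 times (adjusted p = 0.0028 and 0.00336), with 9 and 11 intervals by Vmn2r7, 5 and 8 by Vmn2r60, and 6 and 7 by Vmn2r71. The vomeronasal deficit did not pass among intervals at or above the median fold (0.949 and 0.922 times, adjusted p = 0.830 and 0.602) or over gene bodies alone (0.835 and 0.853 times, 0.161 for each), and in MEFs not with list-only intervals (0.813 times, 0.0624). Within 25 kb of the TSS, against lists not matched on gene length, the olfactory receptor density was close to random in MEFs (0.998 times, adjusted p = 0.954) and below random in mESCs (0.938 times, 0.0313). There the mESC share of these genes passed as lower than random (0.974 times, 0.0313). Their mESC density passed among intervals at or above the median fold (1.27 times, 0.0042), and their MEF density did not pass with list-only intervals (1.12 times, 0.0748). Against lists shifted along the gene order, the mESC density of the Zfp genes passed (1.20 times, adjusted p = 0.0084). Shifted lists keep such clusters together but are not matched on territory length. The Zfp MEF density kept its size and did not pass (1.14 times, 0.109), and neither did the vomeronasal deficit (0.743 and 0.781 times, 0.201 for each). The olfactory receptor excess was gone (1.02 and 0.982 times, 0.811 for each). Whether the kept clusters or the missing length match removed it was not tested. The Zfp densities did not pass with GC matching (1.02 and 1.07 times, adjusted p = 0.805 and 0.213) or over gene bodies alone (1.10 and 1.15 times, 0.316 and 0.119), and in MEFs not among intervals at or above the median fold (1.15 times, 0.102).

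**Figure D5:**
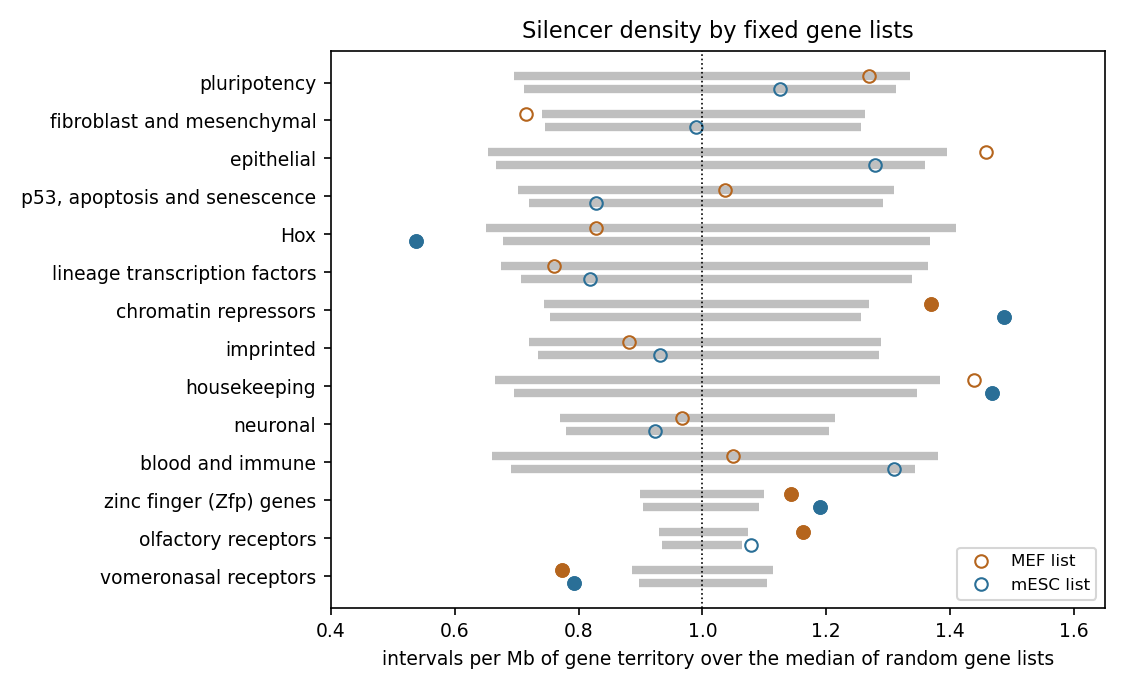
Silencer intervals per Mb of gene territory over the median of 10000 random lists matched on length (horizontal axis, 1 means as at random) for 14 gene lists (vertical axis). Circles are the MEF and mESC lists, filled where the adjusted permutation p is under 0.05, and grey bars hold 95% of the random lists; chromatin repressors stand at 1.37 and 1.49.

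Pluripotency genes did not stand apart in either cell type. Their 36 members held 80 MEF and 94 mESC intervals, 1.27 and 1.12 times random densities (adjusted p = 0.244 and 0.571), with an mESC share of 54.0% (adjusted p = 0.542). Among the factors that define or induce pluripotency, Pou5f1 had 0 MEF and 3 mESC intervals, Sox2 had 0 and 1, Nanog had 5 and 2, Myc had 1 and 1, and Klf4 had none in either list (0 and 0). Tet1, a DNA demethylase gene, had 12 and 14, Esrrb 6 and 5, and Fbxo15 4 and 7. Epithelial genes, which switch on early in reprogramming of fibroblasts, had 68 MEF and 79 mESC intervals (1.46 and 1.28 times, adjusted p = 0.0792 and 0.248). Their MEF density passed with GC matching (1.55 times, adjusted p = 0.030) and among intervals at or above the median fold (1.87 times, adjusted p = 0.0308). Cdh1, the gene for E-cadherin, had 8 MEF and 8 mESC intervals, the tight junction genes Tjp1 and Ocln had 13 and 11 and 8 and 7. The list of p53, apoptosis and senescence genes had 79 and 83 (1.04 and 0.828 times, adjusted p = 0.844 and 0.419). Trp53 had 1 MEF and 2 mESC intervals, Cdkn1a and Cdkn2a each had 2 and 1, Trp63 had 9 and 11, Rb1 had 10 and 8, and Bcl2 had 6 and 10. None of these 3 lists passed in the mESC share either.

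Neuronal, blood, imprinted and lineage genes did not stand apart in density or mESC share. Neuronal genes are long and held 558 MEF and 680 mESC intervals (0.967 and 0.923 times random densities, adjusted p = 0.838 and 0.623), among them 90 and 121 by Cntnap2, 88 and 100 by Dlg2 and 62 and 73 by Csmd1. Blood and immune genes held 51 and 84 (1.05 and 1.31 times, adjusted p = 0.838 and 0.174), with 7 and 8 by Ptprc, 4 and 10 by Tlr4 and 4 and 9 by Adgre1. Of 33 imprinted genes, 31 were in the protein-coding annotation and held 81 and 111 (0.882 and 0.932 times, adjusted p = 0.569 and 0.724), with 10 and 16 by Usp29, 6 and 13 by Kcnq1 and 8 and 10 by Plagl1. Lineage transcription factor genes held 39 and 56 (0.760 and 0.818 times, adjusted p = 0.301 and 0.425), with 3 and 4 by Gsc and 3 and 3 by both Elf5 and Gata3.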

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

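The tests of repeats and of read depth on the X chromosome, of composition behind the overlap, and of GC, repeats and consensus composition behind the AP-1 difference were chosen only after the result was seen. No biological explanation was tested with replicates, since each cell type had 1 list.

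Differences between the cell types singled out 10 values, of which 9 compare mESC-only with MEF-only silencers. The mESC-only over MEF-only ratio of match shares was 0.788 for AP-1, 0.907 for TEAD, 0.809 for the MYC-type E-box, 0.216 for NFI, 0.911 for BCL6/STAT and 0.988 for CpG, all more frequent in MEF-only windows. It was 1.21 for KLF/SP and 1.18 for ZFP57, which were more frequent in mESC-only windows. TEAD and ZFP57 did not pass in windows under 50% soft-masked, and BCL6/STAT, NFI and CpG did not pass in whole intervals, where the CpG ratio was 1.01. Whole intervals were not matched on length between the classes. They held a CpG in 60.7% (MEF-only) and 61.0% (mESC-only), against 60.4% and 62.2% of random sequence of the same lengths. The CpG ratio of 1.01 is therefore not a reversal. The mESC share of intervals by fibroblast and mesenchymal genes, over all intervals and against random gene lists, was 64.2%. Its ratio to random kept its size but did not pass with list-only intervals or against lists shifted along the gene order. The soft-masked excess over random was 4.65 percentage points larger in mESC-only than in MEF-only intervals.

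AP-1 sites were more frequent in windows centred on MEF-only than on mESC-only silencers, and within strata of GC and soft-masked share the odds ratio was 0.808 (95% interval 0.767 to 0.852), which argues against GC and repeats as the whole cause. Of all 641 scrambled consensuses of the same letters, 20 (3.12%) differed between the classes by as large a ratio, under the 5% set for composition as the cause, and 18 of the 20 can hold a CpG, which the AP-1 consensus cannot. Random draws of 100 scrambles had been tried before all were counted and the 5% was set. If AP-1 marked the MEF calls of higher fold, the match share would be higher there, and this rise was not seen. MEF-only intervals had a match in 5.11% of the top 20% of folds and 5.69% of the lowest 20%. The ratio was 0.897 (Fisher exact p = 0.0766). The rule written beforehand counted an equal or lower share in the top 20% as against AP-1 marking the calls of higher fold. The share was lower, but a Fisher exact p under 0.05 was also required when it was judged. The fall did not reach that, so the question stays open. In mESC-only intervals the ratio was 0.890 (Fisher exact p = 0.0307), so a fall with fold was not particular to MEFs. The share in MEF-only windows was 0.983 times that of shuffled sequence, and what sets the classes apart stays open.

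The X chromosome held 3.40 and 3.42 times fewer MEF and mESC silencers per Mb than the autosomes. Repeats were not the whole cause, since over sequence that is not soft-masked the ratio was still 2.87 and 2.97. Composition was also excluded as the whole cause, since autosomal bins matched to 139 of 150 X bins on GC and repeats held 3.03 and 3.07 times as many intervals. Lower read depth on the X chromosome may explain part of the deficit, because it was 5.57 and 6.07 times among intervals in the lowest of 3 fold classes and 1.24 and 1.47 times among those with a fold above 4. This gradient does not single out depth. From the lowest to the highest 10% of folds, soft-masked share rose from 34.4% to 46.7% in MEFs and from 36.5% to 50.5% in mESCs. The X chromosome was 46.8% soft-masked, against at most 35.8% of any autosome, and the matched bins were not split by fold. The lists give neither depth nor the sex of the DNA source, so lower depth stays a hypothesis.

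The overlap of the MEF and mESC lists was far above random placement. Placement matched on GC and soft-masked share still left it 18.6 and 18.4 times random, so composition and repeats were not the whole cause. Chance in the input libraries, if both lists were made against the same ones, cannot be told apart from shared silencer activity. Both would make the folds of overlapping intervals rise together (Spearman rho = 0.498), and the lists hold no counts with which to split the input.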

How the results depend on the processing

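The alternatives with list-only intervals, with gene lists shifted along the gene order and with placement matched on GC and repeats were chosen after seeing the data. The shifted lists were also not matched on territory length. No paired analysis was possible because the lists hold no values per library, and leaving out each replicate was not possible for the same reason. Where no cause is given, the cause was not tested.

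Overlap, clustering, fold medians, base composition, 1 Mb bins and the count of single genes kept direction and side of the threshold under every alternative run. Without each chromosome in turn the overlap stayed between 22.9 and 23.5 times random in MEFs and between 22.8 and 23.3 in mESCs.

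Among intervals at or above the median fold, the autosomal over X density was 2.56 in MEFs and 2.49 in mESCs, and the intergenic deficit no longer passed (0.998 and 0.995). With promoters of 5 kb either side the promoter deficit no longer passed (0.990 and 0.997), since the wider window adds flanks that are not depleted near the TSS. With GC-matched placement the MEF 3 prime UTR share passed (1.12).

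Against dinucleotide-shuffled sequence, 14 motifs passed in MEF-only windows instead of 7, and 12 in shared windows instead of 7. The ratio moved to the other side of 1 for several motifs, at times only just (ZFP57 at 0.987 in mESC-only windows), and the cause was not tested. In MEF-only windows these were AP-1 (0.983), TEAD (0.938), the OCT octamer (1.26), ESRRB (1.51), CREB/ATF (2.03), ZFP57 (0.783), RUNX (1.17), MEF2 (0.781) and BCL6/STAT (1.16). In mESC-only windows they were the OCT octamer (1.27), ESRRB (1.27), ZFP57 (0.987), the MYC-type E-box (2.54), RUNX (1.12), BCL6/STAT (1.12) and NR2F DR1 (ratio 9). In shared windows they were AP-1 (0.932), the OCT octamer (1.08), ESRRB (1.32), ZFP57 (0.813), the MYC-type E-box (3.14), RUNX (1.16) and BCL6/STAT (1.12). With windows under 50% soft-masked, 4 motifs passed in shared windows. The ratio moved to about 1 for the OCT octamer (1.01), GATA (1.01) and CpG (0.999) in mESC-only windows. It did so for GATA (1.00) and CpG (0.994) in shared windows. In whole intervals, which were not matched on length between the classes, the CpG ratio of mESC-only over MEF-only was 1.01. The AP-1, KLF/SP and MYC-type E-box differences between MEF-only and mESC-only windows passed in whole intervals and in windows under 50% soft-masked.

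Of the 14 gene lists, 4 passed in MEF density. This fell to 1 over gene bodies alone, 2 among intervals at or above the median fold, 1 with list-only intervals and 0 against shifted lists. In mESC density 5 passed, and 1, 2, 3 and 2 did under the same alternatives, with 2 under GC matching. In mESC share 1 list passed, 2 did within 25 kb of the TSS, and 0 did with list-only intervals and against shifted lists. Some MEF densities passed only under an alternative. Those of fibroblast, Hox and housekeeping genes did so within 25 kb of the TSS, where the random lists were not matched on gene length. That of epithelial genes did so with GC matching and among intervals at or above the median fold. Chromatin repressors no longer passed in mESC density among intervals at or above the median fold (1.42 times). The mESC share of fibroblast and mesenchymal genes did not pass with list-only intervals (1.16 times) or against shifted lists (1.13 times). Within 25 kb of the TSS the olfactory receptor density was close to random in MEFs (0.998 times) and below random in mESCs (0.938 times).

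Depth limits every interval in a way the lists do not show, since they give no counts.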

Other observations

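Listed intervals were depleted within 1 kb of the start sites of genes against placement that was not matched on GC or on library coverage. Within 1 kb of the TSS of a protein-coding gene, MEF and mESC intervals stood at 0.586 and 0.631 times 10 random placements, at 0.985 and 1.05 times from 1 to 2 kb, and at 1.10 and 1.12 times from 2 to 5 kb. Beyond 100 kb they stood at 0.933 and 0.918 times. CpG-rich promoters (7435) held 0.507 times the expected MEF intervals (95% Poisson interval 0.445 to 0.572) and 0.557 times the expected mESC intervals (0.499 to 0.617), and CpG-poor promoters (14476) held 0.632 and 0.651 times. These values were not matched on GC either, and GC matching left little of the deficit over promoters of all genes (0.949 and 0.965 times).

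On the X chromosome 50.3% of MEF and 39.1% of mESC intervals overlapped the other list, against 47.2% and 36.6% on the autosomes. The values in this part were computed after the data were seen.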
